A study of Mus musculus with 16 samples.

How the data were processed

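Polysome-bound and total RNA were profiled by sequencing in the prelimbic cortex (PL) of C57BL/6J mice, an inbred strain. Per the labels' protocols, a Cre-dependent virus carrying a fusion of green fluorescent protein and a large-subunit ribosomal protein was injected in PL. A canine adenovirus carrying Cre, which travels back along axons, was injected in the nucleus accumbens (NAc), the basolateral amygdala (BLA) or the ventral tegmental area (VTA). Tagged polysomes were pulled down with anti-GFP beads, so that the immunoprecipitate (IP) is enriched in mRNA of PL neurons that project to the injected target, and the Input is the total RNA of the surrounding PL. This viral form of translating ribosome affinity purification is called vTRAP. Libraries were made with the SMARTer Ultra Low RNA kit and Nextera XT, per the labels' protocols. This chemistry does not mark the strand.

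The 16 samples formed 6 groups, IP and Input for each of 3 projections, taken from the sample titles. PL-NAc and PL-BLA had 3 IP and 3 Input libraries each, and PL-VTA had 2 and 2. The labels do not say whether replicates came from separate animals or pools, so p-values for genes measure only the spread between these samples, which may be technical. Those for gene lists compare the members with other genes at a preset correlation. They treat genes that move together as nearly independent, and do not measure spread between samples or animals. The values used were the authors' comparison tables, 1 for each projection, with 39017 gene rows each. No per-library values were used here.

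Reads were aligned with STAR 2.3, counted with featureCounts and compared with DESeq2 on builds named mm10 and GRCm38, per the submitters' processing notes. The versions of featureCounts and DESeq2, the annotation release, the strand setting, the filters and the model formula are not given in the sources used here. The mean signal per gene is the authors' mean of normalized read counts over the libraries of a comparison, per the file headers. The log2 fold change and its standard error are the authors' values, per the file headers. The direction is not named in the headers and was read from the values as IP over Input, because glial and mitochondrially encoded transcripts were negative. The fold changes of genes with a single read lay at 0.05 or -0.03 in PL-NAc, so the deposited log2 values appear to have been shrunken toward 0 by the authors. They understate the change of genes with low counts, and can also understate that of abundant genes with a wide spread between libraries. In PL-VTA the standard error was 0.449 for Slc35d3 at a mean of 247.71 and also for Ppp1r1b at a mean of 12400. The test score is the Wald statistic of the authors, which equalled the fold change divided by its standard error in the deposited values. The p-value and the adjusted p-value are those deposited by the authors, and recomputing them gave the two-sided normal p of that statistic and its Benjamini-Hochberg adjustment. The adjusted p is blank in the deposited tables for genes below a mean of 1.82 in PL-NAc, 2.39 in PL-BLA and 8.58 in PL-VTA, and those genes were not called.

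Depth can be read only in part from such tables. The mean normalized counts summed to 15437849 in PL-NAc, 16347808 in PL-BLA and 16520414 in PL-VTA, which stand for the average library of each comparison. Genes with a single read in a single library gave the size factors, which measure relative depth. They ranged from 0.789 to 1.19 over the 6 PL-NAc libraries, from 0.850 to 1.17 over the 6 PL-BLA libraries and from 0.893 to 1.14 over the 4 PL-VTA libraries. The 10 most abundant genes took 3.91%, 4.13% and 4.03% of the mean counts in the order PL-NAc, PL-BLA and PL-VTA. Rows without a gene symbol held 0.240%, 0.227% and 0.235%. The median standard error of the log2 fold change over genes with a mean of at least 50 was 0.124 in PL-NAc, 0.129 in PL-BLA and 0.219 in PL-VTA, so that PL-VTA detected only larger changes.

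Before the data were examined, the tests, the gene lists, the rule for named genes and most alternatives were fixed. That plan put a count model first in case counts were present, and used comparison tables otherwise; the second form was used. A gene was called higher or lower in the IP at an adjusted p under 0.05 in the authors' deposited table. Differences between projections were tested per gene with a two-sided Wald z, the difference of the log2 fold changes over the root of the summed squared standard errors, with Benjamini-Hochberg adjustment over 21981 genes for PL-NAc and PL-BLA, 21559 for PL-NAc and PL-VTA and 21613 for PL-BLA and PL-VTA. The projections share no library. Gene lists were tested with cameraPR of limma 3.58.1 on the Wald statistic with a preset inter-gene correlation of 0.01, which compares the members with all other genes. Adjustment was over 75 tests for the 25 lists in 3 projections, and again over 75 for the 3 pairs. The correlation between genes could not be estimated without per-library values, so 0.05 was tried as an alternative.

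The lists were markers of astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, red blood cells and choroid plexus, inhibitory neurons, excitatory neurons, and upper-layer intratelencephalic, layer 5 extratelencephalic, layer 5 intratelencephalic, and layer 6 corticothalamic and layer 6b neurons. Functional lists were immediate early genes, presynaptic proteins, glutamate receptors and postsynaptic scaffolds, GABA receptors, neuromodulator and peptide receptors, neuropeptides, voltage-gated sodium, potassium and HCN channels, interferon response and antigen presentation, and unfolded protein and integrated stress response. The remaining lists were nuclear noncoding RNAs, mitochondrially encoded mRNAs, cytosolic ribosomal proteins and nuclear-encoded oxidative phosphorylation. Named genes were, for each projection, the 6 largest changes in each direction among called genes with a mean of at least 50, and the 2 members of each list with the smallest p. For each pair, the 5 largest called differences in each direction with a mean of at least 50 in both tables were named. Predicted gene models, numbered clones and pseudogenes were passed over for naming. Slc17a7, Camk2a, Gad1, Gad2, Mbp, Gfap, Cx3cr1, Cldn5 and Rpl10a were named everywhere. Any other gene named was chosen after its values were seen. A few genes that the rule would name are not reported here.

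On simulated data for PL-NAc and PL-BLA (21981 genes), the test of differences recovered 32% of genes changed by 0.5, 82% by 1 and 100% by 2 on the log2 scale, with 11 false calls. For PL-NAc and PL-VTA (21559 genes) it recovered 6%, 56% and 90%, with 4 false calls. For PL-BLA and PL-VTA (21613 genes) the shares were 10%, 56% and 98%, with 3 false calls. The list test, tested on simulated data for the 17998 PL-NAc genes in 100 draws, gave p under 0.05 for 4.04% of unchanged lists and recovered 96% of shifted ones. These simulations met the assumptions of the tests, with normal noise at the deposited standard errors for differences and independent genes for lists. Changed genes had means of at least 50. Error rates with correlated genes, shrunken fold changes or misjudged standard errors were therefore not measured.

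Coordinates are from GENCODE M21 on GRCm38, which held 37693 of the 39017 gene identifiers, 37278 of them under the same symbol. Because the strand setting is not given, reads of genes whose exons overlap a gene on the opposite strand cannot be assigned with certainty, among them Junb with Prdx2, Syn2 with Timp4, Ddit3 with Mars, Atp5d with Cbarp, mt-Nd5 with mt-Nd6, and Cdkn1c, Cux1, Pou3f1, Fgfr3, Grm2 and Gabra5 with predicted or noncoding genes. Reads of near-identical copies, such as the hemoglobin genes and ribosomal protein pseudogenes, can also be split by the counting. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 were used. Alternatives were adjustment over all genes with a p-value, a minimum mean of 50, an adjusted p under 0.01, an absolute log2 fold change of at least 1, centring and scaling of fold changes, ranks or fold changes in the list test, and a correction for transcript length chosen after seeing the data.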

Results

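The series compared RNA bound to tagged polysomes of PL projection neurons (IP) with the total RNA of the surrounding PL (Input), for projections to NAc, BLA and VTA. Each projection had its own libraries, 3 IP and 3 Input for PL-NAc and PL-BLA, and 2 of each for PL-VTA. The mean normalized counts summed to 15437849, 16347808 and 16520414 in the authors' deposited tables for PL-NAc, PL-BLA and PL-VTA. Reads were detected for 23202, 23343 and 22606 genes, of which 17998, 17668 and 15440 carried an adjusted p. Values for genes are log2 fold changes of IP over Input with the authors' standard errors (SE).

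The first comparison asked which transcripts the polysomes of PL neurons projecting to NAc carried more or less of than the tissue around them. Glial transcripts fell. Because the sign of the tables was read from glial and mitochondrially encoded transcripts, their fall in each projection was set by that reading and is no finding of its own. All 16 astrocyte, 18 oligodendrocyte and 17 microglial markers were lower in the PL-NAc IP in the authors' deposited table, with medians of -1.91, -3.05 and -2.65, or 26.5%, 12.1% and 15.9% of Input. Among them was Mbp, myelin basic protein, at -2.73 (SE 0.06) in the authors' deposited table. The astrocyte filament gene Gfap was -2.23 (SE 0.10), the metabolic enzyme Aldoc -1.59 (SE 0.06) and the sphingosine receptor S1pr1 -3.03 (SE 0.12) in the authors' deposited table. Microglial genes included the chemokine receptor Cx3cr1 at -2.56 (SE 0.23) and the complement genes C1qb at -3.05 (SE 0.18) and C1qc at -3.38 (SE 0.21) in the authors' deposited table. Excitatory neuron markers rose, with 10 of 15 higher and 2 lower, and the vesicular glutamate transporter Slc17a7 stood at 0.62 (SE 0.06) in the authors' deposited table.

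Across all genes, 3848 were higher and 3903 lower in the PL-NAc IP among 17998 tested, at an adjusted p under 0.05 by the submitters' model, in the authors' deposited table. Larger changes were mostly decreases, with 303 genes at least 2-fold higher and 1927 at least 2-fold lower. The largest decreases were in transcripts of the mitochondrial genome, led by mt-Cytb (chromosome M, 14145 to 15288), a subunit of respiratory complex III, at -7.11 (SE 0.16), and the ribosomal RNAs mt-Rnr2 at -6.66 (SE 0.26) and mt-Rnr1 at -6.63 (SE 0.16), in the authors' deposited table. Then came mt-Nd1 at -6.42, mt-Nd4 at -6.40 and mt-Nd5 at -6.30 in the authors' deposited table. Vegfd (ENSMUSG00000031380, chromosome X, 164373378 to 164402650), a lymphatic growth factor, rose most at 2.87 (SE 0.23), or 7.30-fold, with an adjusted p of 4.8e-34 in the authors' deposited table. Nnmt, nicotinamide N-methyltransferase, followed at 2.51 (SE 0.26), and Wfdc18 at 2.49 (SE 0.20), in the authors' deposited table. The cyclin-dependent kinase inhibitor gene Cdkn1c was 2.24 (SE 0.13), Dancr 2.06 (SE 0.20) and Nol8 2.05 (SE 0.12) in the authors' deposited table.

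Among other non-neuronal lists in PL-NAc, 8 of 9 oligodendrocyte precursor markers, 13 of 18 endothelial and mural markers and 6 of 7 markers of red blood cells and choroid plexus fell, and none rose. Bcan was -1.57 (SE 0.09), Gpr17 -2.19 (SE 0.22), the smooth muscle light chain Myl9 -2.23 (SE 0.21), and Vtn -2.26 (SE 0.22) in the authors' deposited table. The tight junction gene Cldn5 was -1.60 (SE 0.36) and the hemoglobin genes Hbb-bs -4.08 (SE 0.22) and Hba-a1 -3.78 (SE 0.29) in the authors' deposited table. Of 20 interferon and antigen presentation genes 10 fell and none rose, led by Ifitm3 at -2.24 (SE 0.22) and H2-D1 at -0.91 (SE 0.10) in the authors' deposited table. Of 22 inhibitory neuron markers 21 fell, including Calb2, which encodes calretinin, at -3.64 (SE 0.11) in the authors' deposited table. The GABA-synthesizing enzymes Gad1 and Gad2 were -1.24 (SE 0.07) and -1.40 (SE 0.09) in the authors' deposited table. The exception, looked up after the count was seen, was Sst, somatostatin, at 0.26 (SE 0.09) in the authors' deposited table. All of these lists were lower than other genes by limma cameraPR. The adjusted p were 2.5e-44 for astrocytes, 2.4e-81 for oligodendrocytes, 3.1e-05 for their precursors and 2.6e-16 for microglia by limma cameraPR. For endothelial and mural cells, red blood cells and choroid plexus, inhibitory neurons and interferon genes they were 0.00108, 4.6e-06, 8.9e-34 and 0.00456 by limma cameraPR.

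Of the excitatory markers in PL-NAc, the transcription factor Neurod6 was 0.999 (SE 0.07), Lingo1 0.78 (SE 0.07) and the kinase gene Camk2a 0.17 (SE 0.07) in the authors' deposited table (list adjusted p 6.5e-05, limma cameraPR). Layer markers separated. Upper-layer intratelencephalic markers fell, with 9 of 13 lower and 2 higher, such as the transcription factor Cux1 at -1.39 (SE 0.09), while Lmo4 rose at 0.92 (SE 0.06), in the authors' deposited table (list adjusted p 0.00309, limma cameraPR). Layer 5 intratelencephalic markers rose, with 6 of 10 higher and 1 lower, including the troponin gene Tnnc1 at 1.84 (SE 0.11) and Dkkl1 at 1.77 (SE 0.10) in the authors' deposited table (list adjusted p 0.00356, limma cameraPR). Layer 5 extratelencephalic markers were split, with 5 of 16 higher, 4 lower and 7 not called. The subcerebral fate regulator Fezf2 was 1.57 (SE 0.08) and Crym, a thyroid hormone-binding protein, 1.54 (SE 0.08) in the authors' deposited table. For this list the median was negative, -0.11, while limma cameraPR on the statistic was positive with an adjusted p of 0.0231. Of 13 layer 6 and 6b markers 5 rose and 2 fell, with Ctgf at 0.95 (SE 0.12) and Sulf1 at 1.18 (SE 0.18) in the authors' deposited table, and the list did not pass (adjusted p 0.161, limma cameraPR).

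Immediate early genes, the first to respond to neuronal activity, rose in the PL-NAc IP, with 15 of 19 higher and none lower. Junb was 1.05 (SE 0.06) and Egr4 0.94 (SE 0.08) in the authors' deposited table (list adjusted p 1.5e-06, limma cameraPR). Of 72 nuclear-encoded oxidative phosphorylation genes 64 rose and 2 fell, and of 76 cytosolic ribosomal protein genes 49 rose and none fell (list adjusted p 4.1e-19 and 5.1e-07, limma cameraPR). Examples were Ndufa4 at 0.82 (SE 0.06), Atp5d at 0.84 (SE 0.07), Rpl41 at 1.27 (SE 0.09) and Rps15 at 0.97 (SE 0.09), while Rpl10a, of the protein family carried by the tag, was -0.09 (SE 0.28) and not called, in the authors' deposited table. All 8 mitochondrially encoded mRNAs fell, with a median of -6.21 or 1.35% of Input, and 8 of 9 nuclear noncoding RNAs fell, with Malat1 at -6.25 (SE 0.15) and Meg3 at -4.60 (SE 0.10) in the authors' deposited table (list adjusted p 9.6e-86 and 2.5e-34, limma cameraPR).

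Neuropeptide genes went both ways in PL-NAc, with 10 of 16 lower and 4 higher (list adjusted p 0.00628, limma cameraPR). Vip was -2.61 (SE 0.13) and Cck, cholecystokinin, 0.92 (SE 0.07) in the authors' deposited table. Of 26 ion channel genes 14 fell and 3 rose, with Scn4b at -2.09 (SE 0.13) and Scn1a at -1.12 (SE 0.11) in the authors' deposited table (list adjusted p 0.0140, limma cameraPR). Of 18 presynaptic genes 10 rose, including Syn2 at 0.93 (SE 0.06) and Sv2b at 0.78 (SE 0.06), and 7 fell, in the authors' deposited table (list adjusted p 0.0290, limma cameraPR). The other 4 lists did not pass in PL-NAc by limma cameraPR. Glutamate receptors and scaffolds had 9 of 26 higher and 3 lower (adjusted p 0.465), GABA receptors 3 of 14 and 5 (0.806), neuromodulator and peptide receptors 9 of 41 and 9 (0.686), and stress response genes 6 of 15 and 3 (0.918). Members called included Grm2 at 0.66 (SE 0.09), Grin1 at 0.53 (SE 0.07), Gabbr2 at 0.41 (SE 0.07) and Gabra5 at 0.45 (SE 0.08) in the authors' deposited table. Further members were Sstr2 at 1.03 (SE 0.11), Cckbr at 0.85 (SE 0.07), Atf4 at -0.85 (SE 0.09) and Ddit3 at -1.29 (SE 0.14) in the authors' deposited table. For neuromodulator receptors the median, -0.04, and the test differed in sign. Adjusted over the list alone, counts in PL-NAc were the same except for 14 lower endothelial and mural markers, 7 higher layer 5 intratelencephalic markers, 17 higher immediate early genes, 54 higher ribosomal protein genes, and 65 higher and 3 lower oxidative phosphorylation genes. With a preset correlation of 0.05, extratelencephalic markers (adjusted p 0.0779), presynaptic genes (0.0923) and channels (0.0798) no longer passed by limma cameraPR, nor did the first 2 on ranks (0.886 and 0.285), presynaptic genes at a mean of at least 50 (0.122) and channels after length correction (0.102). On fold changes these 3 lists (adjusted p 0.220, 0.308 and 0.445) and upper-layer markers (0.0666) did not pass and layer 6 markers did (0.0158), by limma cameraPR.

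**Figure D1:**
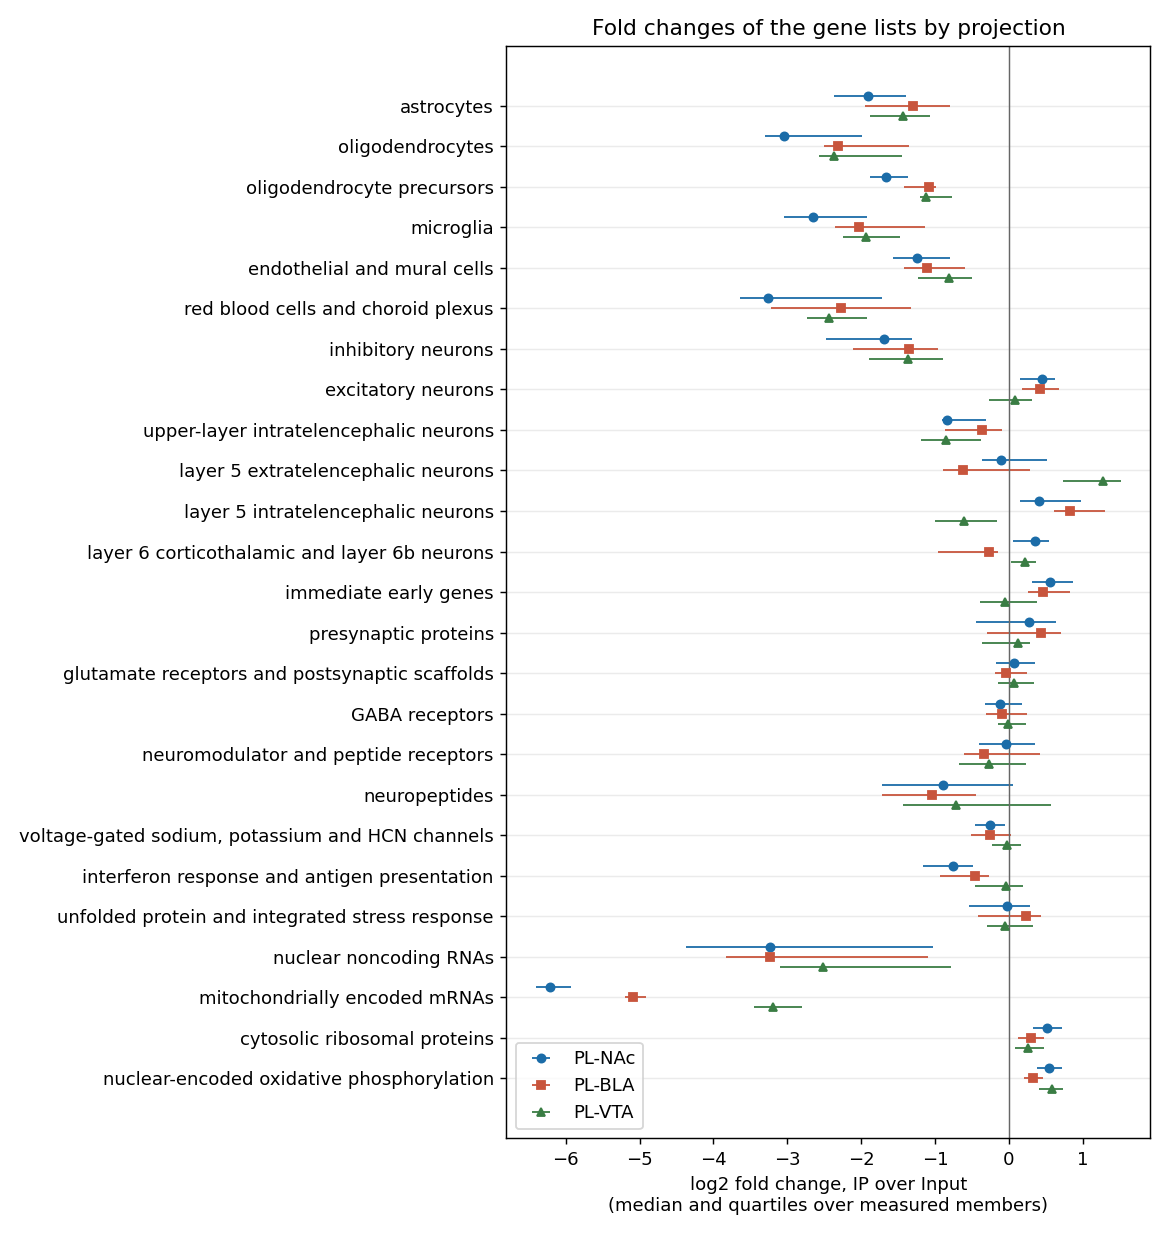
Median log2 fold change of IP over Input (points) and quartiles (lines) over the measured members of each of the 25 gene lists (vertical axis), in PL-NAc (circles), PL-BLA (squares) and PL-VTA (triangles). Glial lists lie left of 0 in each projection, and mitochondrially encoded mRNAs move from -6.21 in PL-NAc to -5.09 in PL-BLA and -3.19 in PL-VTA.

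The second comparison asked the same of neurons projecting to BLA. Glial markers again fell, with 15 of 16 astrocyte, 18 of 18 oligodendrocyte and 16 of 17 microglial markers lower in the PL-BLA IP and none higher, at medians of -1.30, -2.31 and -2.03 in the authors' deposited table. Layer 5 intratelencephalic markers rose in 8 of 10 cases, led by Dkkl1 at 1.95 (SE 0.11) and Tnnc1 at 1.60 (SE 0.11), in the authors' deposited table. Layer 6 markers fell, with 6 of 13 lower and 2 higher, among them the vesicle protein Syt6 at -1.87 (SE 0.15) and the transcription factor Foxp2 (chromosome 6, 14901349 to 15441977) at -1.75 (SE 0.17), in the authors' deposited table. The immunoglobulin heavy chain gene Igha (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236) rose most, at 4.61 (SE 0.29) or 24.4-fold, in the authors' deposited table.

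In all, 3671 genes were higher and 3573 lower in the PL-BLA IP among 17668 tested in the authors' deposited table, 284 and 1620 of them at least 2-fold. After Igha came Vegfd at 2.89 (SE 0.22), the autophagy enzyme gene Atg7 at 2.77 (SE 0.10), Susd5 at 2.46 (SE 0.15), Wfdc18 at 2.38 (SE 0.19) and Pik3r6 at 2.32 (SE 0.16) in the authors' deposited table. Decreases were led by mt-Rnr1 at -6.65 (SE 0.15), mt-Rnr2 at -6.53 (SE 0.25) and Malat1 at -5.93 (SE 0.21) in the authors' deposited table, followed by mt-Nd5 at -5.35, mt-Cytb at -5.26 and mt-Co1 at -5.17. All 8 mitochondrially encoded mRNAs and 8 of 9 nuclear noncoding RNAs fell, including mt-Nd2 at -5.11 (SE 0.26), Meg3 at -4.66 (SE 0.10) and Snhg11 at -3.24 (SE 0.11) in the authors' deposited table (list adjusted p 6.0e-31 and 4.9e-37, limma cameraPR).

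The strongest glial decreases by p in PL-BLA were S1pr1 at -2.26 (SE 0.12) and Fgfr3 at -2.13 (SE 0.14) for astrocytes, and Mbp at -2.53 (SE 0.06) and Mal at -3.01 (SE 0.12) for oligodendrocytes, in the authors' deposited table. For microglia they were the complement genes C1qc at -3.02 (SE 0.20) and C1qb at -2.38 (SE 0.17) in the authors' deposited table (list adjusted p 4.1e-19, 4.3e-41 and 5.5e-14, limma cameraPR). Gfap was -2.01 (SE 0.25) and Cx3cr1 -1.73 (SE 0.21) in the authors' deposited table. Of 9 oligodendrocyte precursor markers 8 fell, such as C1ql1 at -2.33 (SE 0.26) and Bcan at -0.72 (SE 0.10), in the authors' deposited table. The 1 that rose, looked up after the count was seen, was Cspg4 at 1.02 (SE 0.25) in the authors' deposited table. Endothelial and mural markers fell in 12 of 18 cases, with Myl9 at -1.93 (SE 0.18), Rgs5 at -1.42 (SE 0.19) and Cldn5 at -1.39 (SE 0.33), in the authors' deposited table. Red blood cell and choroid plexus markers fell in 6 of 8, with Hbb-bs at -4.15 (SE 0.24) and Hba-a1 at -3.16 (SE 0.27), in the authors' deposited table. Their list adjusted p were 0.00165, 0.000395 and 7.0e-07 by limma cameraPR. Of 22 inhibitory markers 21 fell, including the parvalbumin gene Pvalb at -3.02 (SE 0.14), Calb2 at -2.46 (SE 0.13), Gad1 at -0.70 (SE 0.16) and Gad2 at -0.84 (SE 0.09), in the authors' deposited table (list adjusted p 2.9e-25, limma cameraPR).

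Excitatory markers rose in 11 of 15 cases and fell in 2 in the PL-BLA IP, with Neurod6 at 1.34 (SE 0.08), Lingo1 at 1.30 (SE 0.07) and Slc17a7 at 0.75 (SE 0.06) in the authors' deposited table (list adjusted p 6.1e-06, limma cameraPR). Camk2a, at 0.06 (SE 0.16), was not called in the authors' deposited table. Layer 5 intratelencephalic and layer 6 lists passed at adjusted p of 1.9e-05 and 0.01002 by limma cameraPR. Layer 5 extratelencephalic markers had 8 of 16 lower and 4 higher and did not pass as a list (median -0.63, adjusted p 0.371, limma cameraPR). Within it Pou3f1 (chromosome 4, 124656807 to 124660655), a POU transcription factor, was -1.65 (SE 0.13), and S100a10 was 1.41 (SE 0.10), in the authors' deposited table. Upper-layer markers had 8 of 13 lower and 2 higher, with Cux1 at -1.55 (SE 0.09) and Lmo4 at 0.84 (SE 0.07) in the authors' deposited table (list adjusted p 0.0480, limma cameraPR).

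Immediate early genes rose in 13 of 19 cases with none lower, and presynaptic genes in 11 of 18 with 5 lower (list adjusted p 1.3e-05 and 0.000718, limma cameraPR). Egr4 was 1.06 (SE 0.09), Junb 1.01 (SE 0.08), Syn2 1.16 (SE 0.06) and Sv2b 0.88 (SE 0.07) in the authors' deposited table. Oxidative phosphorylation genes rose in 57 of 74 cases and fell in 2, and ribosomal protein genes rose in 28 of 76 and fell in 2 (list adjusted p 8.5e-10 and 0.00332, limma cameraPR). Atp5d was 0.69 (SE 0.07), Rpl41 0.80 (SE 0.09) and Rps15 0.63 (SE 0.09), whereas Cox6a2, the heart and muscle form of a cytochrome oxidase subunit, was -2.76 (SE 0.25), in the authors' deposited table. Rpl10a was -0.18 (SE 0.27) and not called in the authors' deposited table. Neuropeptide genes fell in 12 of 16 cases and rose in 3, with Vip at -2.48 (SE 0.14) and Tac1 at -1.92 (SE 0.11), in the authors' deposited table (list adjusted p 0.000128, limma cameraPR). Channels fell in 13 of 26 cases and rose in 2, with Scn4b at -2.01 (SE 0.10) and Scn1a at -0.98 (SE 0.11), in the authors' deposited table (list adjusted p 0.00257, limma cameraPR).

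The remaining lists did not pass in PL-BLA by limma cameraPR. Glutamate receptors and scaffolds had 8 of 26 higher and 5 lower (adjusted p 0.552), GABA receptors 4 of 14 and 5 (0.856), neuromodulator receptors 11 of 41 and 11 (0.812), interferon genes 0 of 20 and 8 (0.0546), and stress response genes 8 of 15 and 3 (0.580). Among their members Grm2 was 0.98 (SE 0.09), Grm8 1.01 (SE 0.15), Gabbr2 0.70 (SE 0.07), Cckbr 0.95 (SE 0.08) and Sstr2 0.98 (SE 0.11) in the authors' deposited table. Lower were the antiviral gene Ifitm3 at -2.004 (SE 0.24), Ifi27l2a at -1.89 (SE 0.42), Atf4 at -0.93 (SE 0.09) and Ddit3 at -1.56 (SE 0.14) in the authors' deposited table. Medians and tests differed in sign for glutamate receptors (median -0.04), GABA receptors (-0.10) and neuromodulator receptors (-0.33). Adjusted over the list alone, counts in PL-BLA were the same except for 1 higher astrocyte marker, 7 lower markers of red blood cells and choroid plexus, 1 higher inhibitory marker, 15 lower neuromodulator receptors, 13 lower neuropeptide genes, 4 lower stress response genes, and 58 higher and 3 lower oxidative phosphorylation genes. Upper-layer markers (adjusted p 0.107) and ribosomal protein genes (0.0871) no longer passed with a preset correlation of 0.05, nor did upper-layer markers at a mean of at least 50 (0.0590) or after length correction (0.133) and presynaptic genes on ranks (0.0861), by limma cameraPR. On fold changes upper-layer markers (adjusted p 0.285), layer 6 markers (0.194), presynaptic genes (0.166) and channels (0.302) did not pass, whereas interferon genes passed there (0.00482), on ranks (0.00503) and after length correction (0.0273), by limma cameraPR.

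The third comparison concerned neurons projecting to VTA. Layer 5 extratelencephalic markers rose in 12 of 15 cases with none lower, at a median of 1.27 or 2.41-fold, in the authors' deposited table. Fezf2 (ENSMUSG00000021743, chromosome 14, 12342094 to 12348189) rose most of all named genes, at 2.94 (SE 0.15) or 7.67-fold with an adjusted p of 4.4e-77, and Crym was 2.16 (SE 0.14), in the authors' deposited table. Layer 5 intratelencephalic markers fell in 4 of 10 cases and rose in 1, with Tnnc1 (chromosome 14, 31208312 to 31211729) at -2.48 (SE 0.33) and Myl4 at -1.25 (SE 0.23) in the authors' deposited table. Upper-layer markers fell in 9 of 13 cases with none higher, including the transcription factor Rorb at -1.51 (SE 0.22) and Cux1 at -1.19 (SE 0.18) in the authors' deposited table. These lists passed at adjusted p of 1.5e-22, 0.0140 and 2.9e-06 by limma cameraPR.

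In the PL-VTA IP 1702 genes were higher and 1623 lower among 15440 tested in the authors' deposited table, 226 and 1009 of them at least 2-fold. Further increases were Dlk1, a Notch ligand relative, at 2.69 (SE 0.34), Krt2 at 2.60 (SE 0.43), the carbohydrate sulfotransferase gene Chst8 at 2.46 (SE 0.19), Atg7 at 2.45 (SE 0.17) and the melanocortin receptor gene Mc4r at 2.36 (SE 0.29) in the authors' deposited table. The largest decreases were mt-Rnr2 at -5.60 (SE 0.24), mt-Rnr1 at -4.90 (SE 0.27), mt-Cytb at -4.21 (SE 0.36), the microRNA host gene Mir124a-1hg at -3.93 (SE 0.37), Meg3 at -3.75 (SE 0.17) and Malat1 at -3.73 (SE 0.40) in the authors' deposited table. All 8 mitochondrially encoded mRNAs and 7 of 9 nuclear noncoding RNAs fell, with mt-Co1 at -3.62 (SE 0.38) and Snhg11 at -2.52 (SE 0.17) in the authors' deposited table (list adjusted p 8.9e-17 and 2.0e-22, limma cameraPR).

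All 16 astrocyte and 18 oligodendrocyte markers and 15 of 17 microglial markers fell in the PL-VTA IP, at medians of -1.44, -2.37 and -1.93 (list adjusted p 1.4e-31, 2.1e-58 and 4.0e-17, limma cameraPR). Fgfr3 was -2.61 (SE 0.20), Gfap -2.58 (SE 0.21), Mobp -2.59 (SE 0.14) and Mbp -2.43 (SE 0.12) in the authors' deposited table. In microglia C1qc was -2.67 (SE 0.28), C1qb -2.15 (SE 0.25) and Cx3cr1 -1.48 (SE 0.31) in the authors' deposited table. Oligodendrocyte precursor markers fell in 6 of 9 cases, endothelial and mural markers in 5 of 15 and markers of red blood cells and choroid plexus in 6 of 7, with none higher (list adjusted p 0.00242, 0.000221 and 1.0e-10, limma cameraPR). Gpr17 was -1.74 (SE 0.32), Bcan -0.90 (SE 0.17), Ly6c1 -2.65 (SE 0.42) and Myl9 -1.95 (SE 0.28) in the authors' deposited table. Cldn5 was -1.14 (SE 0.42), Hbb-bs -3.31 (SE 0.30) and Ttr, the choroid plexus carrier transthyretin, -2.89 (SE 0.27) in the authors' deposited table. Inhibitory markers fell in 17 of 22 cases with none higher, led by the neuropeptide Y gene Npy at -3.07 (SE 0.17) and Pvalb at -2.65 (SE 0.21) in the authors' deposited table (list adjusted p 1.3e-23, limma cameraPR). Gad1 was -0.63 (SE 0.16), and Gad2, at -0.20 (SE 0.42), was not called, in the authors' deposited table.

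Excitatory markers did not move as a list in PL-VTA, with 3 of 15 higher and 4 lower (adjusted p 0.470, limma cameraPR) and a median of 0.08 opposite in sign to the test. The zinc transporter gene Slc30a3 was -2.07 (SE 0.16), Neurod6 -0.82 (SE 0.15) and Camk2a -0.37 (SE 0.13), while Slc17a7, at 0.16 (SE 0.12), was not called, in the authors' deposited table. Of 13 layer 6 markers 1 rose and 2 fell, with Cplx3 at -0.99 (SE 0.24) and Rprm at -0.77 (SE 0.21) in the authors' deposited table (list adjusted p 0.649, limma cameraPR). Among 19 immediate early genes 2 rose and 2 fell, with Egr4 at 0.79 (SE 0.16) and Arc at -0.91 (SE 0.14) in the authors' deposited table (list adjusted p 0.919, limma cameraPR, opposite in sign to the median of -0.06). Oxidative phosphorylation genes rose in 58 of 72 cases and fell in 1, and ribosomal protein genes rose in 11 of 75 with none lower (list adjusted p 2.0e-22 and 0.00309, limma cameraPR). Ndufa4 was 1.08 (SE 0.13), Cox6a2 -2.83 (SE 0.35), Rpl41 1.09 (SE 0.16) and Rpl15 0.74 (SE 0.20), and Rpl10a, at -0.06 (SE 0.39), was not called, in the authors' deposited table.

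Neuropeptide genes fell in 8 of 16 cases and rose in 3 in PL-VTA (list adjusted p 0.000326, limma cameraPR), with Npy and Vip lowest at -3.07 (SE 0.17) and -2.56 (SE 0.21) in the authors' deposited table. Picked after their values were seen, Grp, gastrin-releasing peptide, and Adcyap1, which encodes the peptide PACAP, rose at 2.19 (SE 0.29) and 2.08 (SE 0.21) in the authors' deposited table. Beside the peptide, receptor and channel lists, several transcripts abundant in striatal neurons had wide errors in PL-VTA, chosen after their values were seen: Tac1 0.51 (SE 0.45), Drd1 0.56 (SE 0.45), Scn4b 0.04 (SE 0.40) and Pdyn 1.42 (SE 0.39) in the authors' deposited table. Others of this kind were negative, Penk at -0.88 (SE 0.35) and Drd2 at -0.99 (SE 0.35), in the authors' deposited table. The other lists did not pass by limma cameraPR. Presynaptic genes had 4 of 18 higher and 4 lower (adjusted p 0.812), glutamate receptors and scaffolds 4 of 26 and 2 (0.544), and GABA receptors 1 of 14 and 0 (0.636). Neuromodulator receptors had 5 of 39 higher and 10 lower (adjusted p 0.552, limma cameraPR), channels 2 of 26 and 3 (0.806), interferon genes 0 of 17 and 3 (0.237), and stress response genes 4 of 15 and 3 (0.919). Members called included Syp at 0.69 (SE 0.12), Pclo at -1.26 (SE 0.20), Grik2 at 1.03 (SE 0.21) and Gria4 at -0.86 (SE 0.19) in the authors' deposited table. Gabra5 was 0.90 (SE 0.17), Cckbr 1.198 (SE 0.16), Oprl1 0.77 (SE 0.17), Kcnh1 -0.88 (SE 0.19) and Scn2b 0.66 (SE 0.16) in the authors' deposited table. Ifitm3 was -2.19 (SE 0.35), Ifit3 -1.52 (SE 0.36), Atf4 -0.75 (SE 0.15) and Ddit3 -1.11 (SE 0.22) in the authors' deposited table. Medians and tests differed in sign for GABA receptors (-0.01) and stress response genes (-0.05). Adjusted over the list alone, counts in PL-VTA were the same except for 16 lower microglial markers, 1 higher and 18 lower inhibitory markers, 5 higher and 5 lower presynaptic genes, 9 lower neuropeptide genes, 9 higher ribosomal protein genes, and 62 higher and 2 lower oxidative phosphorylation genes. Ribosomal protein genes did not pass with a preset correlation of 0.05 (adjusted p 0.0845, limma cameraPR), and with only 2 libraries per group the median SE was 0.219 against 0.124 in PL-NAc.

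**Figure D2:**
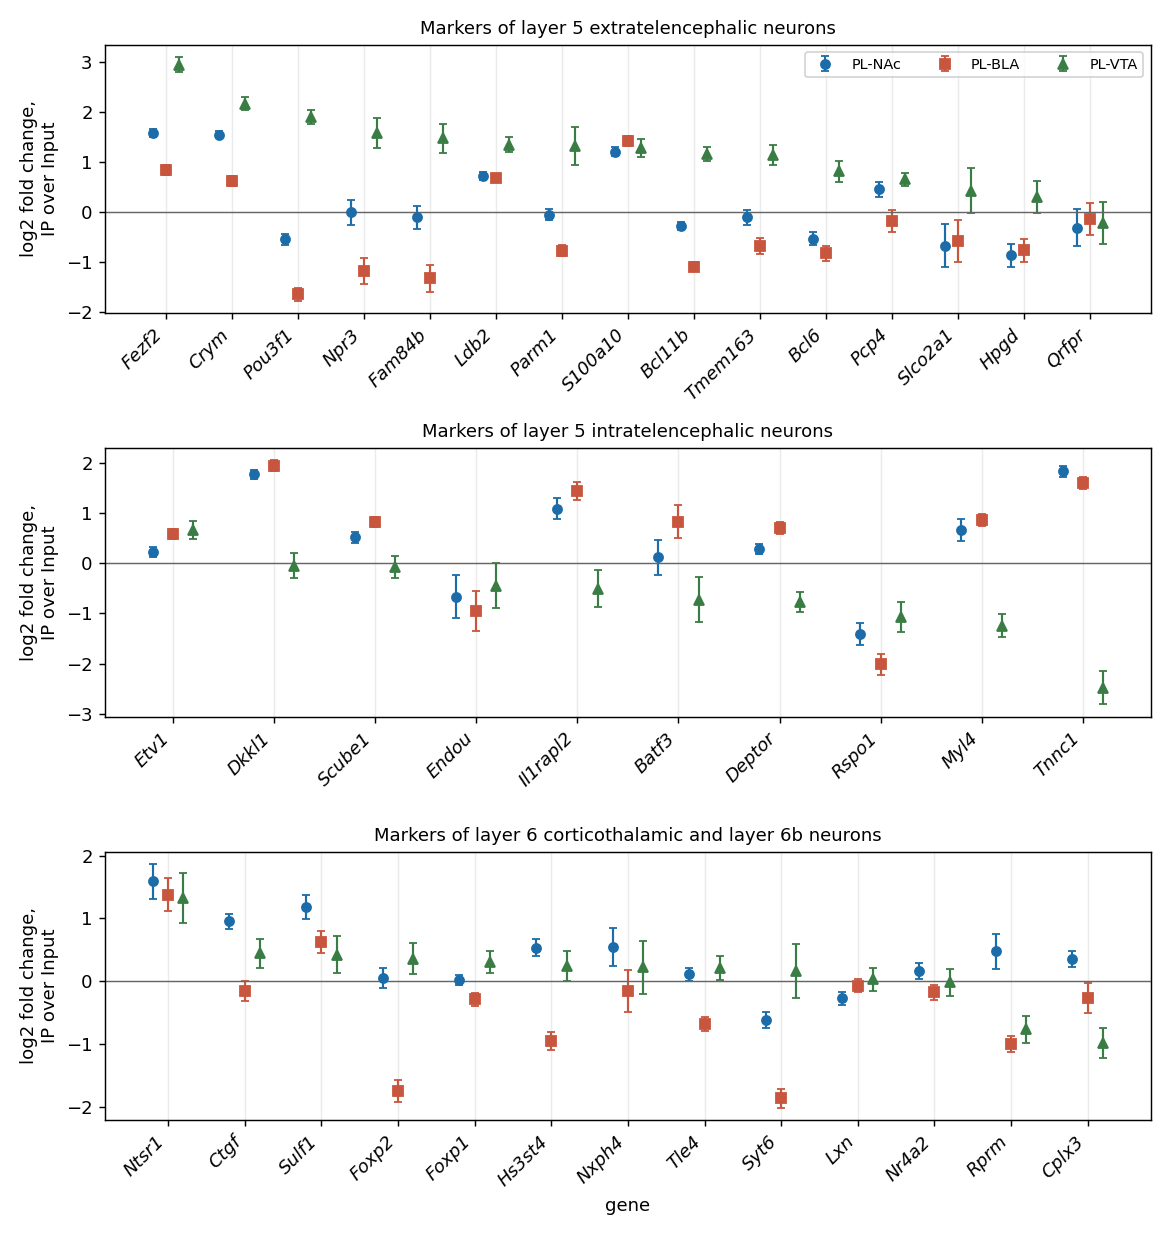
Log2 fold change of IP over Input (points) with the authors' SE (bars) for markers of layer 5 extratelencephalic (top), layer 5 intratelencephalic (middle) and layer 6 corticothalamic and layer 6b neurons (bottom) in PL-NAc, PL-BLA and PL-VTA. Fezf2 lies at 1.57, 0.84 and 2.94, Tnnc1 at 1.84, 1.60 and -2.48, and Foxp2 at 0.06, -1.75 and 0.36.

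Many of the calls were common to the projections. Among 15425 genes with an adjusted p in every table, 1351 were higher and 1332 lower in all 3 IPs in the authors' deposited tables. Independent lists would share 99.4 and 89.4, but all 3 IPs were set against total RNA of the same region. Effects of the pull-down itself were thus not separated from enrichment in the neurons. Fold changes fell with transcript length in each table, at Spearman's rho of -0.193, -0.150 and -0.170 in PL-NAc, PL-BLA and PL-VTA. The shared genes included Atg7, at 1.91 (SE 0.08), 2.77 (SE 0.10) and 2.45 (SE 0.17), and Mbp, at -2.73, -2.53 and -2.43, in the order PL-NAc, PL-BLA and PL-VTA in the authors' deposited tables. Genes called in opposite directions numbered 18 for PL-NAc and PL-BLA, 69 for PL-NAc and PL-VTA, and 115 for PL-BLA and PL-VTA. Across the 11937 genes with a mean of at least 50 in every table, fold changes correlated with Pearson's r of 0.930, 0.837 and 0.781 and Spearman's rho of 0.897, 0.783 and 0.726 in the same order of pairs. Genes are not independent replicates, and no p is given for these correlations.

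**Figure D3:**
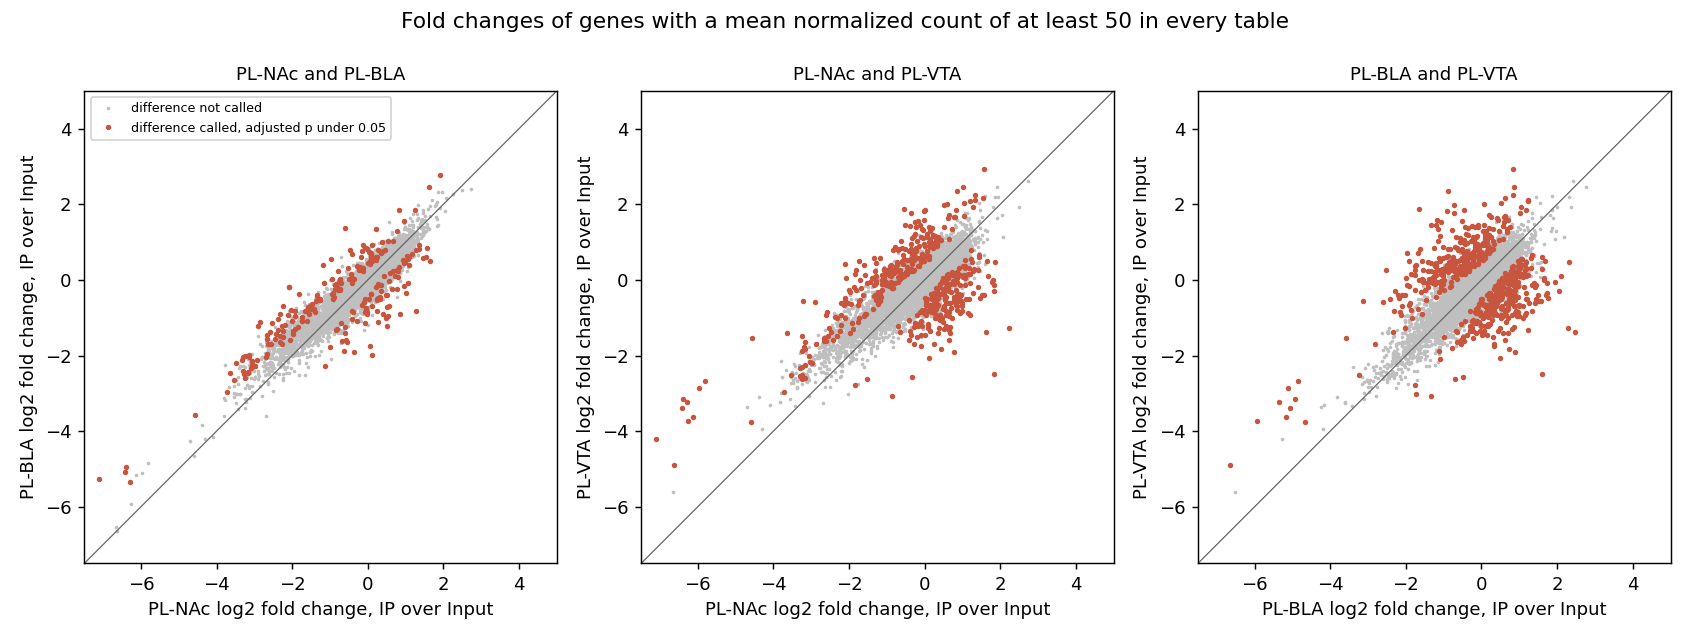
Log2 fold changes of IP over Input in pairs of projections, each point being 1 of 11937 genes with a mean normalized count of at least 50 in every table. Red points are genes whose fold changes differed (241, 463 and 598 from left to right), grey points are the others, and the diagonal marks equality.

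Neurons projecting to NAc and to BLA were compared by the difference of their log2 fold changes, PL-NAc minus PL-BLA, from the authors' deposited tables. In each pair, higher means a larger ratio of IP to Input. Because each projection has its own Input, a difference between the Inputs can also give such a result. Layer 6 and layer 5 extratelencephalic markers were higher in PL-NAc, at median differences of 0.70 and 0.60, with 6 of 13 and 5 of 16 members called and none the other way (adjusted p 8.0e-26 and 2.8e-16, limma cameraPR). Foxp2 differed by 1.80 (SE 0.23), as a value of 0.06 in PL-NAc stood against -1.75 in PL-BLA, in the authors' deposited tables. Glial decreases were deeper in PL-NAc, at median differences of -0.68 for astrocytes, -0.73 for oligodendrocytes, -0.58 for their precursors and -0.76 for microglia (adjusted p 1.0e-29, 5.2e-26, 0.000906 and 4.7e-10, limma cameraPR). Mitochondrially encoded mRNAs were lower in PL-NAc by a median difference of -0.96, and inhibitory neuron markers by -0.39, beside these glial differences (adjusted p 8.8e-12 and 2.5e-06, limma cameraPR).

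By gene, 86 were higher in PL-NAc and 165 in PL-BLA among 21981 tested by the two-sided Wald z with Benjamini-Hochberg adjustment. The largest differences toward PL-NAc were the homeobox gene Sebox at 2.10 (SE 0.42), the neurexophilin gene Nxph3 at 2.09 (SE 0.26), Foxp2, Mc4r at 1.74 (SE 0.42) and Sla at 1.71 (SE 0.33), from the authors' deposited tables. Toward PL-BLA they were Igha at -2.90 (SE 0.38), the collagen gene Col4a1 at -1.98 (SE 0.37), the phosphatase gene Dusp10 at -1.92 (SE 0.32), the immunoglobulin light chain gene Igkc at -1.90 (SE 0.32) and mt-Cytb at -1.85 (SE 0.36), from the authors' deposited tables. Igkc had a mean count of 330.81 at -2.10 in PL-NAc and of 68.5 at -0.20 in PL-BLA, so its Input signal was higher in PL-NAc. Ribosomal protein and oxidative phosphorylation genes were higher in PL-NAc by 0.26 and 0.24 at the median (adjusted p 6.0e-11 and 8.5e-18, limma cameraPR). Upper-layer markers (-0.21, adjusted p 0.00115), presynaptic genes (-0.11, 0.00277), interferon genes (-0.36, 0.0167) and stress response genes (-0.17, 0.0374) were lower in PL-NAc by limma cameraPR. With a preset correlation of 0.05 the last 2 no longer passed (adjusted p 0.0738 and 0.102, limma cameraPR), and on ranks the precursor markers (0.0723) and stress response genes (0.0621) did not. Layer 5 intratelencephalic markers, not passing otherwise (adjusted p 0.0940), were lower in PL-NAc when scaled (0.0395), by limma cameraPR.

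For neurons projecting to NAc and to VTA, PL-NAc minus PL-VTA, layer 5 extratelencephalic markers were higher in PL-VTA at a median difference of -1.24, with 10 of 15 members called, and layer 5 intratelencephalic markers were higher in PL-NAc at 0.95, with 5 of 10 called (adjusted p 8.8e-29 and 4.7e-15, limma cameraPR). Excitatory markers and immediate early genes were higher in PL-NAc, at 0.43 and 0.53, with 6 of 15 and 6 of 19 members called and none the other way (adjusted p 1.4e-14 and 6.7e-13, limma cameraPR). Tnnc1 differed by 4.32 (SE 0.35), from 1.84 in PL-NAc to -2.48 in PL-VTA, in the authors' deposited tables. Mitochondrially encoded mRNAs were less depleted in PL-VTA, at a median difference of -3.05, and nuclear noncoding RNAs at -0.86 (adjusted p 1.5e-32 and 2.5e-06, limma cameraPR). Beside them, astrocyte, oligodendrocyte, precursor and microglial markers were less depleted in PL-VTA by -0.50, -0.67, -0.54 and -0.80 (adjusted p 4.2e-06, 2.2e-14, 0.0105 and 4.6e-05, limma cameraPR). Stronger shrinkage of the deposited fold changes in PL-VTA, considered below, could add to these differences and was not tested.

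Among 21559 genes, 219 were higher in PL-NAc and 275 in PL-VTA by the two-sided Wald z with Benjamini-Hochberg adjustment. After Tnnc1 the largest toward PL-NAc were Cdkn1c at 3.50 (SE 0.37), Susd5 at 2.99 (SE 0.43), the interleukin subunit gene Il12a at 2.68 (SE 0.46) and Tcap at 2.25 (SE 0.34), from the authors' deposited tables. Toward PL-VTA they were mt-Nd4 at -3.24 (SE 0.41), mt-Nd6 at -3.14 (SE 0.49), mt-Nd2 at -3.13 (SE 0.48), mt-Nd5 at -3.08 (SE 0.42) and Cdr1, a neuronal locus that also yields a circular RNA, at -3.04 (SE 0.47), from the authors' deposited tables. Also lower in PL-NAc were markers of red blood cells and choroid plexus (-0.96, adjusted p 0.00296), inhibitory neurons (-0.55, 0.0404), channels (-0.19, 0.00317) and interferon genes (-0.54, 0.00193), by limma cameraPR. Scn4b, a channel gene also abundant in striatal neurons, was -2.09 (SE 0.13) in PL-NAc and 0.04 (SE 0.40) in PL-VTA in the authors' deposited tables. Another striatal transcript, Adora2a, chosen after its values were seen, was -1.66 (SE 0.23) and -2.24 (SE 0.29) in the authors' deposited tables. Whether RNA of striatal cells in PL-VTA, considered below, added to the inhibitory neuron difference was not tested. Higher in PL-NAc were upper-layer markers (0.07, adjusted p 0.0117), layer 6 markers (0.27, 0.0404), presynaptic genes (0.08, 0.0176) and ribosomal protein genes (0.24, 9.9e-06), by limma cameraPR. Neuropeptide genes passed in the positive direction (adjusted p 0.0420, limma cameraPR) against a negative median of -0.27, and turned negative on ranks (0.377). Inhibitory (adjusted p 0.136), layer 6 (0.102), presynaptic (0.0728) and neuropeptide lists (0.119) did not pass with a preset correlation of 0.05, nor did upper-layer (0.118), layer 6 (0.224) and presynaptic lists (0.0673) on ranks, where endothelial and mural markers passed (0.0223), by limma cameraPR. Scaled to equal spread, inhibitory (adjusted p 0.758), precursor (0.0516) and layer 6 lists (0.0558) did not pass, and mean shifts of the statistic shrank from -1.75 to -0.89 for astrocytes, -2.71 to -1.57 for oligodendrocytes, -1.52 to -0.94 for microglia, -0.72 to -0.11 for inhibitory neurons and -2.32 to -1.37 for nuclear noncoding RNAs, by limma cameraPR.

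The last pair, PL-BLA minus PL-VTA, showed the widest separation of layer 5 markers. Layer 5 extratelencephalic markers were higher in PL-VTA at a median difference of -1.64, with 10 of 15 called, and layer 5 intratelencephalic markers higher in PL-BLA at 1.52, with 6 of 10 called (adjusted p 5.3e-54 and 8.6e-18, limma cameraPR). Pou3f1 differed by -3.53 (SE 0.19), from -1.65 in PL-BLA to 1.89 in PL-VTA, with an adjusted p of 2.4e-69 by the two-sided Wald z from the authors' deposited tables. Excitatory markers, upper-layer markers and immediate early genes were higher in PL-BLA at 0.44, 0.28 and 0.50 (adjusted p 2.7e-14, 2.5e-05 and 4.9e-09, limma cameraPR). Layer 6 markers were higher in PL-VTA at -0.38, with 4 of 13 called (adjusted p 5.6e-05, limma cameraPR).

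Of 21613 genes, 337 were higher in PL-BLA and 323 in PL-VTA by the two-sided Wald z with Benjamini-Hochberg adjustment. Toward PL-VTA the largest after Pou3f1 were Mc4r at -3.25 (SE 0.43), Fam84b at -2.79 (SE 0.40), Syndig1l at -2.78 (SE 0.47) and the natriuretic peptide receptor gene Npr3 at -2.75 (SE 0.39), from the authors' deposited tables. Syndig1l belongs to the striatal transcripts with wide errors in PL-VTA, at 0.26 (SE 0.45) in the authors' deposited table. Toward PL-BLA they were Tnnc1 at 4.09 (SE 0.35), Susd5 at 3.83 (SE 0.42), Cdkn1c at 3.54 (SE 0.37), Il12a at 2.80 (SE 0.47) and Slc30a3 at 2.57 (SE 0.18), from the authors' deposited tables. Mitochondrially encoded mRNAs (-1.73, adjusted p 6.6e-10), nuclear noncoding RNAs (-0.72, 3.0e-06), oxidative phosphorylation genes (-0.20, 7.3e-08) and channels (-0.18, 0.00317) were lower in PL-BLA by limma cameraPR. Among channels, Scn4b was -2.01 (SE 0.10) in PL-BLA and 0.04 (SE 0.40) in PL-VTA in the authors' deposited tables. Presynaptic genes (0.12, adjusted p 0.000241) and astrocyte markers (0.23, 0.0182) were higher in PL-BLA by limma cameraPR, and astrocyte markers did not pass with a preset correlation of 0.05 (0.0706).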

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

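All tests of explanations in this part were chosen after the results were seen. Those on carry-over were also widened to the uncertainty of Malat1 after a first outcome had excluded carry-over in PL-VTA, and those on standard errors were split by list after a joint outcome of 1.17. The outcome for mitochondrially encoded mRNAs was left open only once their SE in the other projections had been seen.

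PL-NAc and PL-BLA differed in 86 genes higher in the first and 165 higher in the second by the two-sided Wald z. For each pair, higher again means a larger ratio of IP to Input. Differences toward PL-NAc were Sebox 2.10, Nxph3 2.09, Foxp2 1.80, Mc4r 1.74 and Sla 1.71. Those toward PL-BLA were Igha -2.90, Col4a1 -1.98, Dusp10 -1.92, Igkc -1.90 and mt-Cytb -1.85. Median differences of cell type lists were -0.68 for astrocytes, -0.73 for oligodendrocytes, -0.58 for oligodendrocyte precursors, -0.76 for microglia and -0.39 for inhibitory neurons. Layer lists stood at -0.21 for upper layers, 0.60 for layer 5 extratelencephalic and 0.70 for layer 6 markers. Functional lists stood at -0.11 for presynaptic, -0.36 for interferon and -0.17 for stress response genes. Mitochondrially encoded mRNAs were at -0.96, ribosomal protein genes at 0.26 and oxidative phosphorylation genes at 0.24.

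PL-NAc and PL-VTA differed in 219 genes higher in the first and 275 higher in the second by the two-sided Wald z. Toward PL-NAc were Tnnc1 4.32, Cdkn1c 3.50, Susd5 2.99, Il12a 2.68 and Tcap 2.25. Toward PL-VTA were mt-Nd4 -3.24, mt-Nd6 -3.14, mt-Nd2 -3.13, mt-Nd5 -3.08 and Cdr1 -3.04. Cell type lists had medians of -0.50 for astrocytes, -0.67 for oligodendrocytes, -0.54 for their precursors, -0.80 for microglia, -0.96 for red blood cells and choroid plexus, -0.55 for inhibitory and 0.43 for excitatory neurons. Layer lists had medians of 0.067 for upper layers, -1.24 for layer 5 extratelencephalic, 0.95 for layer 5 intratelencephalic and 0.27 for layer 6 markers. Immediate early genes were at 0.53, presynaptic genes at 0.0823, neuropeptides at -0.27, channels at -0.19 and interferon genes at -0.54. Nuclear noncoding RNAs were at -0.86, mitochondrially encoded mRNAs at -3.05 and ribosomal protein genes at 0.24.

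PL-BLA and PL-VTA differed in 337 genes higher in the first and 323 higher in the second by the two-sided Wald z. Higher in PL-BLA were Tnnc1 4.09, Susd5 3.83, Cdkn1c 3.54, Il12a 2.80 and Slc30a3 2.57. Higher in PL-VTA were Pou3f1 -3.53, Mc4r -3.25, Fam84b -2.79, Syndig1l -2.78 and Npr3 -2.75. Among cell type and layer lists, astrocytes were at 0.23, excitatory neurons at 0.44, upper layers at 0.28, layer 5 extratelencephalic at -1.64, layer 5 intratelencephalic at 1.52 and layer 6 markers at -0.38. Immediate early genes were at 0.50, presynaptic genes at 0.12 and channels at -0.18. Nuclear noncoding RNAs were at -0.72, mitochondrially encoded mRNAs at -1.73 and oxidative phosphorylation genes at -0.20.

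The weaker depletion of Malat1 and mitochondrially encoded mRNAs in PL-VTA might come from total RNA carried evenly into that IP, while a real difference between the neurons of each projection was not tested and stays open. Malat1 alone would need 6.29% carry-over, which predicted a glial rise of 0.387 against 0.694 observed over 51 markers, a gap of 0.3071 that ran from 0.039 to 0.490 over the 95% interval of Malat1. With mitochondrially encoded mRNAs setting the share, at 9.76%, the gap was 0.131. Carry-over therefore cannot be told apart from other causes, because the SE of Malat1 is wide and the 2 ways of setting the share differ. Both shares also took the deposited fold changes as true ratios, and the interval makes no allowance for their shrinkage. In PL-BLA the same reasoning predicted a glial rise of 0.0229 against 0.711, a gap of 0.6878. The gap stayed at 0.602 when mitochondrially encoded mRNAs set the share. Taking the deposited ratios as true, even carry-over does not account for the glial difference. Disagreement between the PL-VTA libraries cannot be told apart for mitochondrially encoded mRNAs. Their SE were 2.855 times those of genes of like abundance in PL-VTA but also 2.26 times in PL-NAc and 3.67 times in PL-BLA. For nuclear noncoding RNAs as a list the ratio was 1.087, so their SE were about as wide as those of like genes. Malat1 itself had a wide SE of 0.40. Disagreement that widened the SE of all PL-VTA genes would cancel in this ratio and was not excluded. Unequal shrinkage of the deposited fold changes is a further explanation. Median SE of nuclear noncoding RNAs were 0.15, 0.21 and 0.29 in PL-NAc, PL-BLA and PL-VTA. Those of mitochondrially encoded mRNAs rose in the same order. Stronger shrinkage at wider SE would make depletion look weaker in PL-VTA. It was not tested and stays open, because unshrunken values were not available.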

How the results depend on the processing

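Transcript-length correction was chosen after seeing the data, and the other alternatives before. At an absolute log2 fold change of at least 1, genes higher and lower in IP numbered 303 and 1927 in PL-NAc (3848 and 3903 without it), 284 and 1620 in PL-BLA (3671 and 3573), and 226 and 1009 in PL-VTA (1702 and 1623). At an adjusted p under 0.01, 1099 genes were higher in PL-VTA and 857 in every projection, against 1702 and 1351. At the same limit, 102 genes were higher in PL-BLA than PL-NAc, against 165, and PL-NAc and PL-VTA differed in 145 and 169, against 219 and 275. Signs reversed for 1 called list, neuropeptides between PL-NAc and PL-VTA, at -8.31 on ranks. The remaining reversals were in lists that did not pass. On ranks these were stress response in PL-NAc 0.451, GABA receptors -2.73 and neuromodulator receptors -4.35 in PL-BLA, and excitatory neurons in PL-VTA 1.32. Between PL-BLA and PL-VTA, ranks gave microglia -1.05, inhibitory neurons -7.61, glutamate receptors -1.25 and neuropeptides -6.57, and scaling gave ribosomal proteins -0.00015. On fold changes, values were GABA receptors in PL-NAc 0.0385, neuromodulator receptors in PL-BLA -0.0144, channels in PL-VTA 0.0175 and stress response in PL-VTA -0.0133. With a mean of at least 50 they were GABA receptors in PL-BLA -0.0483 and immediate early genes in PL-VTA -0.0699. Corrected for length they were GABA receptors in PL-NAc 0.0539, and in PL-VTA immediate early genes -0.0112, channels 0.203 and stress response -0.211. The cause was not tested. Of 374 alternatives for lists 335 stayed the same, and of 225 for pairs of projections 202 did. No paired analysis was possible because the tables hold no per-library values. For the same reason leaving out replicates, a replicate block, other normalizations, pseudocounts or count models and an estimated correlation were not run. Depth limits calls for genes of low counts, and its effect was not tested.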

Other observations

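The rise of layer 5 extratelencephalic markers in PL-VTA reached beyond Fezf2 and Crym, with members chosen here after their values were seen. Bcl11b, the transcription factor that directs axons toward the spinal cord, was 1.16 (SE 0.14) in the authors' deposited table for PL-VTA. Pou3f1 was 1.89 (SE 0.14), Npr3 1.57 (SE 0.29) and Fam84b 1.47 (SE 0.29) in the authors' deposited table. Whether RNA of striatal cells, considered below, added to these values or to those of Fezf2 and Crym was not tested. Somatostatin, Sst, also chosen after its values were seen, rose at 0.26 (SE 0.09) in PL-NAc and fell at -0.53 (SE 0.09) in PL-BLA and -1.69 (SE 0.19) in PL-VTA in the authors' deposited tables.

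The tests in this part were written down before their outcomes were computed, but after the patterns that prompted them were seen.

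Transcripts of striatal projection neurons were an unplanned observation in PL-VTA. Mean counts of most striatal markers were highest in PL-VTA. For Ppp1r1b they were 4245, 7040 and 12400 in PL-NAc, PL-BLA and PL-VTA in the authors' deposited tables. Medians over the 16 markers tested below were 379.51, 745.17 and 962.32 in that order. Only Penk, at 1964.9, 5254.5 and 3708, and Drd2, Adora2a and Gpr6 were highest in PL-BLA. A hypothesis is that RNA of striatal cells entered some PL-VTA libraries. The test used 16 striatal markers whose values had not been looked at when it was written. Their SE were 1.993 times those of genes of like abundance in PL-VTA, against 1.02 in PL-NAc and 1.05 in PL-BLA. The median met the prediction of at least 1.5 times, while spread of neuronal subtype markers in general was excluded at 1.05 times. Only 9 of the 16 reached 1.5 times. At low counts the ratio says little, as Ido1 and Isl1 had SE of 0.43 and 0.40 but ratios of 1.04 and 1.13. Gng7, at a high count, had a ratio of 1.11. Adora2a at -2.24 (SE 0.29) and Gpr6 at -0.96 (SE 0.28) in the authors' deposited table for PL-VTA stayed lower with ordinary SE, which the hypothesis leaves unexplained.

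Rpl10a-ps1 (ENSMUSG00000084416, chromosome 1, 64993951 to 64994604), a processed pseudogene, was picked after its values were seen. It stood at 2.74 (SE 0.07), 2.41 (SE 0.25) and 2.63 (SE 0.15) in the authors' deposited tables for PL-NAc, PL-BLA and PL-VTA, while Rpl10a itself was not called. Enrichment of ribosomal protein mRNAs in general was excluded, as the pseudogene lay at least 2.116 above their median. A hypothesis is that reads of the GFP-L10 transgene were counted there, since it is 100% identical to the Rpl10a coding sequence over 654 bases and 0 of 20 other ribosomal protein pseudogenes rose as far. Reads of the endogenous Rpl10a mRNA would be counted at the same place, so its share was not resolved.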
